A study of Xenopus laevis with 5 samples.

How the data were processed

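Ectodermal explants of Xenopus laevis, 5 samples in all, were profiled on single-colour Affymetrix arrays of this frog, 1 array per sample. The titles put 3 samples in the group injected with ICD RNA and 2 in the group injected with ICD and FoxJ1 RNA, and number the replicates within each group. Per the labels, biotin-labelled cRNA was hybridised. The deposited values are 1 signal intensity per probe set on a linear scale, made by the authors with MAS5, per the submitters' processing notes. The version of MAS5 and its settings are not given in the sources used here. The values themselves show that each array had been scaled so that its mean signal, with 2% trimmed at either end, was 200.03, 200.03, 200.03, 200.02 and 200.03. Detection calls were not used here.

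The table held 15611 probe sets, of which 120 were Affymetrix controls and were left out of every test. A table of GEO's platform annotation gave 1 gene symbol for 9304 probe sets, several for 195 and none for 6112. Gene identifiers of 9227 probe sets were found in the RefSeq gene table of assembly Xenopus_laevis_v10.1, which updated 2 symbols and was used for names only. No probe set carried the name foxj1, so the level of FoxJ1 itself was not analysed here. Xenopus laevis has an L and an S copy of many genes, called homeologs. They were counted as separate genes, although a probe set for one copy can also bind RNA of the other.

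The signals were taken as scaled by the authors and compared as log2(signal + 16). The 25% of probe sets with the lowest mean over the 5 arrays were left out, which left 11618. A linear model per probe set was fitted with limma (version 3.58.1, in R 4.3.3) by lmFit and eBayes with a trend of variance on mean signal. The tests were two-sided, with Benjamini-Hochberg adjustment over all probe sets tested and a threshold of 0.05. A log2 difference is ICD with FoxJ1 minus ICD alone, and the added 16 makes it understate the change of dim probe sets. Figures were drawn with matplotlib 3.10.9.

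The labels give 1 comparison, and its tests, the gene lists, the rule for named genes and most alternatives were written before the data were examined. The 14 gene lists were matched to symbols in lower case without the homeolog suffix, a tandem copy number or a provisional tag, and through synonyms that no other gene bears as its own symbol. The symbol esr1, which here names the oestrogen receptor, was taken out of the Notch list before any value was seen. Each gene was represented by its probe set with the highest mean signal. Per list, members higher, lower and not past the threshold were counted, again after adjustment over the list alone. The set was then tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. List p-values were adjusted over the 14 lists. The rule named the 15 genes with the largest rise and the 10 with the largest fall among those past the threshold whose groups did not overlap, and up to 4 members of each list with the smallest p. This gave 77 genes. Genes named outside the rule are said to have been chosen after their values were seen.

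Signal over background took the place of depth. On each array the highest signal among 20 control probe sets for sequences foreign to frog RNA served as the background level, a choice made after seeing the data. It was 28.4, 20.0 and 25.9 on the ICD arrays and 16.9 and 25.3 on the arrays with FoxJ1. Where a probe set lay at or below this level on every array of the dimmer group, the change is given as "at least" a fold, with the dimmer arrays set to the higher of the level and their own signal before logs were averaged. The poly-A control transcripts, bacterial RNAs that are added before labelling, split the arrays. Their median signal over 24 probe sets was 318, 324 and 368 on ICD replicates 1 and 2 and ICD+FoxJ1 replicate 1, but 2.95 and 1.90 on ICD replicate 3 and ICD+FoxJ1 replicate 2. This split, called the labelling batch here, crosses the groups. Another set of control probe sets, for bioB, split the arrays the same way. Its median signal was 86.4, 104.25 and 99.8 on the arrays with poly-A signal, and 227.85 and 250.5 on the others. Whether the batches differ in labelling alone is therefore not known. A fit with it as a block, and a fit of the 3 arrays with poly-A signal, were added after the data had been seen.

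The code was tested on 20 simulated data sets of this comparison, 3 against 2 arrays and 11618 probe sets, of which 200 were changed. It recovered 30.1% of 2-fold, 97.0% of 4-fold and 100% of 16-fold changes. Of its calls, 7.39% were unchanged probe sets, and 0 had the wrong sign. Camera called 100% of the changed and 0% of the unchanged lists. The simulated probe sets varied independently, so this does not test camera on lists whose members vary together. In the data the estimated correlation ran from -0.01 in the mesoderm and endoderm list to 0.83 in the axoneme structure list. The settings tried besides were other pseudocounts (1 and 64), no filter or a filter on 50% of the probe sets, quantile normalization, scaling to the same median, no variance trend, the replicate number as a block, each replicate left out in turn, every probe set of a list member, and camera with an estimated correlation.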

Results

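Transcripts of Xenopus laevis ectodermal explants were measured on 5 Affymetrix arrays, 1 per sample. Embryos received synthetic RNA at the 2-cell stage. Their prospective ectoderm was explanted at stage 9 to 10, kept on fibronectin, and lysed for RNA at stage 22. The injected RNA encoded ICD in 3 samples and ICD plus FoxJ1 in 2 samples. ICD is the usual name in this field for the intracellular domain of Notch, whose activity keeps frog skin progenitors from becoming multiciliated cells, although the labels do not spell it out. FoxJ1 is a forkhead transcription factor known to regulate motile cilia. The comparison asks which genes, in the first place those of cilia, differ when FoxJ1 is added to ICD.

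Median signals per array lay between 62.1 and 73.5, and between 65.3% and 77.3% of the 15491 probe sets other than controls exceeded the background level of their array. Log2 signals correlated across probe sets with r between 0.927 and 0.966 within a group and between 0.840 and 0.903 across groups, and probe sets are not independent replicates. The small number of arrays limits the precision. The labels do not say whether replicates came from separate batches of embryos, so the p-values measure only the spread between these samples, which may be technical. No probe set carried the name foxj1, and its level was not analysed here.

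With FoxJ1, many genes that encode parts of cilia rose. All 27 measured genes of axoneme structure and 12 of 15 genes for axonemal dyneins and their assembly rose. So did 11 of 19 genes for intraflagellar transport and the BBSome. However, the camera call of each of these lists was lost, with an adjusted p = 0.308 with an estimated correlation. Measured genes are those with a probe set left after the dimmest 25% were taken out. With no filter, 26 of 27 axoneme structure genes, 11 of 17 dynein genes and 11 of 20 intraflagellar transport genes rose. The filter thus left out no axoneme structure gene, but it did leave out genes of the other lists. The largest rise was that of ccdc78.S, which encodes a protein of centriole amplification in multiciliated cells. Its signal was 34.2 ± 22.97 (SD, n = 3) with ICD and 2040 ± 77.9 (SD, n = 2) with ICD and FoxJ1. The largest falls among named genes were in mmp3.L, a matrix metalloproteinase, from 822 ± 115 (SD, n = 3) to 59.2 ± 48.0 (SD, n = 2), and in olfm4.L, a secreted olfactomedin, from 1821 ± 413 (SD, n = 3) to 135 ± 51.2 (SD, n = 2).

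Of 11618 probe sets tested with limma, 868 changed, 521 of them higher and 347 lower with FoxJ1, and this balance moved with single arrays: 740 were higher and 647 lower without ICD replicate 1, 374 and 214 without ICD replicate 2, 415 and 169 without ICD replicate 3, 116 and 32 without ICD+FoxJ1 replicate 1, and 156 and 34 without ICD+FoxJ1 replicate 2. By at least 2-fold, 491 rose and 302 fell, and 28 rose by at least 16-fold. A gene name was at hand for 289 of the higher and 224 of the lower probe sets. In all 868, the arrays with FoxJ1 lay entirely above or entirely below those without, which picking them by a small p makes likely. Among all tested probe sets 21.2% lay above and 23.01% below, where chance gives 10% for each. That 10% is an average over the 10 splits of the arrays into 3 and 2. Probe sets vary together on the same arrays, and the excess over 10% was not tested. At background on all ICD arrays were 57 of the higher probe sets, and 32 of the lower ones were at background on both arrays with FoxJ1.

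Among the 15 named genes with the largest rise, 10 belonged to the axoneme structure list and ccdc78.S to the list of centriole genes. Tekt2.S, a tektin of the doublet microtubules, rose by 4.83 (SE 0.43, limma adjusted p = 0.00131) on the log2 scale, from 47.6 ± 29.6 (SD, n = 3) to 1633 ± 54.9 (SD, n = 2). Its homeolog tekt2.L was at background on all 3 ICD arrays and rose at least 17.0-fold. Rsph1.L, a radial spoke head gene, had a signal of 4470 ± 1232 (SD, n = 2) against 229 ± 170 (SD, n = 3), with a log2 difference of 4.52 (SE 0.68, limma adjusted p = 0.00859). Ak7.S, an adenylate kinase of cilia, rose by 4.64, and cfap45.S, cfap161.L and cfap52.S, whose proteins lie on or inside the doublet microtubules, rose by 4.40, 4.40 and 4.28. Tekt4.S rose by 4.16, rsph3.L by 4.12 and nme5.L by 4.08. The 4 genes of this group outside the lists were fam166b.S (4.85), tepp.L (4.38), the GMP reductase gene gmpr2.S (4.36) and the adenylate kinase gene ak1.L (4.09). Of the 50 named genes with the largest rise, 26 belonged to one of the 4 cilium lists. These lists hold 15, 27, 19 and 29 measured genes, and 5915 named genes were tested.

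**Figure D1:**
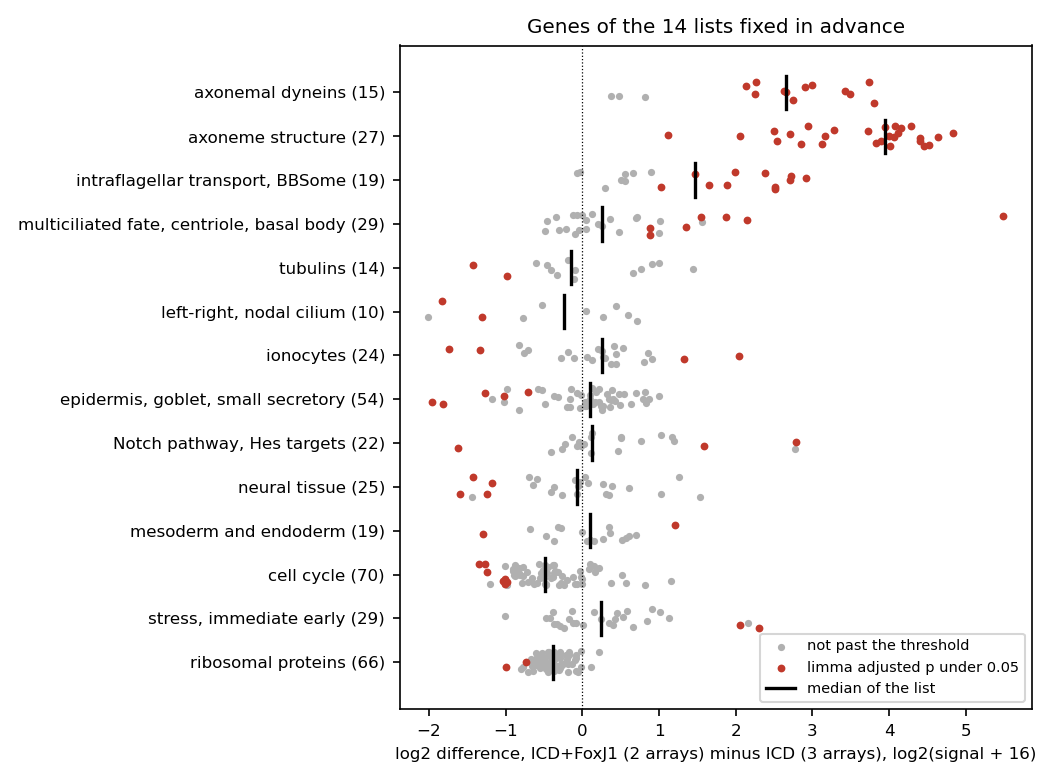
Log2 difference between ICD with FoxJ1 (2 arrays) and ICD alone (3 arrays) for each measured gene of the 14 lists, with the number of genes in brackets. Each point is a gene, red where the limma adjusted p was under 0.05, and the black bar is the median of the list. All 27 axoneme structure genes lie to the right of 0, with a median of 3.95, and the cell cycle and ribosomal protein genes have medians of -0.49 and -0.39.

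The axoneme structure list holds radial spoke, central apparatus, nexin link, tektin and microtubule inner protein genes. Its 27 measured members rose, and the same 27 when adjusted over the list alone, with a median log2 difference of 3.95. Rises ranged from 1.12 in fam161a.L, named after its value was seen, to 4.83 in tekt2.S. Cfap161.L went from 73.5 ± 33.96 (SD, n = 3) to 1783 ± 214 (SD, n = 2), cfap20.L rose by 3.83 and tekt1.L by 4.06. The list stood above other genes in limma's camera (adjusted p = 1.34e-30), a call that was lost with an adjusted p = 0.308 with an estimated correlation. Fry, which asks whether the genes of a set move one way, gave an adjusted p of 0.0222. Its adjusted p was 0.0921 without ICD replicate 2, 0.0600 without ICD replicate 3, 0.187 without ICD+FoxJ1 replicate 1, 0.178 without ICD+FoxJ1 replicate 2 and 0.0512 with the labelling batch as a block, so this call was lost in each. Without ICD+FoxJ1 replicate 1, 16 of the 26 genes then tested rose.

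Of 15 genes for axonemal dyneins and their assembly and docking factors, 12 rose, 0 fell and 3 did not pass the test, and 13 rose when adjusted over the list alone. Dynlrb2.S, a dynein light chain gene, rose by 3.80 (SE 0.39, limma adjusted p = 0.00191), from 135 ± 63.1 (SD, n = 3) to 1944 ± 9.69 (SD, n = 2). Daw1.S, an assembly factor for outer dynein arms, rose by 3.74, dnaaf10.L by 2.75 and odad4.L, of the docking complex, by 2.63. The 3 genes not past the threshold were ruvbl2.S (0.81), dnaaf5.L (0.48) and ruvbl1.S (0.37), named after their values were seen. The median log2 difference was 2.65 (camera adjusted p = 7.49e-15), and the call was lost, with an adjusted p = 0.308 with an estimated correlation. Without ICD+FoxJ1 replicate 1, 7 genes rose.

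In the list for intraflagellar transport, its motors, the BBSome and ciliary GTPases, 11 of 19 genes rose, 0 fell and 8 did not pass the test. Adjusted over the list alone, 12 rose. Bbs5.L, of the BBSome, rose by 2.70 (SE 0.22, limma adjusted p = 0.00131), from 99.9 ± 9.52 (SD, n = 3) to 738 ± 16.1 (SD, n = 2). Arl3.S, a ciliary GTPase gene, rose by 2.91, lztfl1.L, a regulator of the BBSome, by 2.52 and ift80.L by 2.51. The median was 1.47 (camera adjusted p = 2.21e-11), with an adjusted p = 0.308 with an estimated correlation. Without ICD+FoxJ1 replicate 1, 4 genes rose, and without ICD+FoxJ1 replicate 2, 6 rose.

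Of 29 genes for multiciliated cell fate, centrioles and basal bodies, 7 rose, 0 fell and 22 did not pass the test, and 8 rose when adjusted over the list alone. After ccdc78.S, the rises were in pcm1.L, of centriolar satellites (2.15, SE 0.23, limma adjusted p = 0.00207), poc5.L, a centriole gene (1.88), mks1.L, of the transition zone (1.55), and, named after their values were seen, tubd1.L, delta tubulin (1.35), b9d1.L (0.89) and tube1.L, epsilon tubulin (0.88). Also chosen after their values were seen, ccno.L differed by 0.05 (SE 0.85), foxn4.S by -0.06 (SE 0.30), plk4.L by -0.21 (SE 0.22), sass6.L by -0.49 (SE 0.23) and rfx2.S by 1.01 (SE 0.32, limma adjusted p = 0.103). The list had a median of 0.26 (camera adjusted p = 0.00103), with an adjusted p = 0.439 with an estimated correlation. Leaving out either array with FoxJ1 left 2 genes that rose, and 7 rose and 1 fell without ICD replicate 1. Set directly against this list, the axoneme structure genes stood higher in camera with p = 2.23e-09, and with p = 0.117 with an estimated correlation.

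The level of cilium genes differed between the ICD arrays. On ICD replicate 1, all 27 axoneme structure genes were lower than on the other ICD arrays, against 42.2% of all tested probe sets. The median log2 signal of the list was 5.28, 6.40 and 6.74 on ICD replicates 1 to 3, and 10.05 and 9.92 on the arrays with FoxJ1. Of the dynein list 10 of 15 genes, and of the intraflagellar transport list 14 of 19, were lowest on that array, as were 19 of 25 neural genes and 18 of 24 ionocyte genes.

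Of 22 genes of the Notch list, 2 rose, 1 fell and 19 did not pass the test, with the same counts, 2 and 1, when adjusted over the list alone. Hes5.10.L, a Hairy/Enhancer of split repressor gene of the kind that Notch induces, rose by 2.79 (SE 0.35, limma adjusted p = 0.00407), from 243 ± 99.0 (SD, n = 3) to 1677 ± 124 (SD, n = 2). Hes5.2.L, at background on all 3 ICD arrays, rose at least 2.27-fold, and jag1.L, a Notch ligand gene, fell by 1.63. Hes5.1.L had signals of 660.7, 44.7 and 23 on the ICD arrays and 707.4 and 872.9 with FoxJ1, and its log2 difference of 2.78 (SE 1.05) did not pass (limma adjusted p = 0.159). Of the 12 Hes, Hey and Nrarp genes in the list, 10 were highest among the ICD arrays on ICD replicate 1, against 35.5% of all tested probe sets, and without this array 7 genes of the list rose. Without ICD+FoxJ1 replicate 1, 0 rose and 0 fell, and without ICD+FoxJ1 replicate 2, 1 rose and 0 fell. The list's median was 0.12 (camera adjusted p = 0.231).

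**Figure D2:**
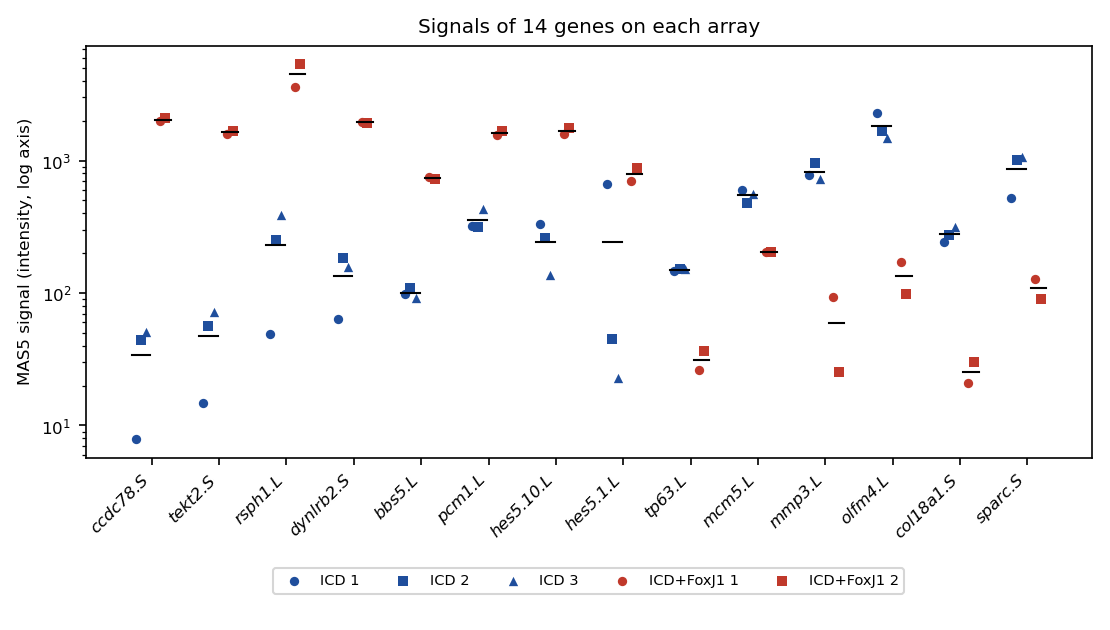
MAS5 signal (log axis) of 14 genes on each array, blue for ICD alone and red for ICD with FoxJ1, with the symbol shape giving the replicate and the black bar the mean of the group. Cilium genes such as ccdc78.S go from a mean of 34.2 to 2040, whereas olfm4.L goes from 1821 to 135. For hes5.1.L, ICD replicate 1 lies at 660.7, near the arrays with FoxJ1.

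After mmp3.L and olfm4.L, the largest falls were in fbn3.L, a fibrillin gene (fell by 3.23), pnhd.L, which encodes a secreted protein of the early embryo (at least 6.64-fold lower, at background on both arrays with FoxJ1), and fstl1.L, a secreted follistatin-like protein (fell by 3.01). Both homeologs of col18a1, a basement membrane collagen, fell. Col18a1.S went from 278 ± 36.3 (SD, n = 3) to 25.6 ± 6.29 (SD, n = 2), a log2 difference of -2.83 (SE 0.24, limma adjusted p = 0.00131), and col18a1.L fell by 2.82. Snai1.S, a transcription factor of epithelial-mesenchymal transition, fell by 2.78, sparc.S, a matrix glycoprotein, by 2.77 and fkbp9.S, a prolyl isomerase of the endoplasmic reticulum, by 2.75.

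Of 54 genes of epidermis, goblet and small secretory cells, 0 rose, 5 fell and 49 did not pass the test, and 6 fell when adjusted over the list alone. Krt19.L, a keratin gene, fell by 1.96 (SE 0.21, limma adjusted p = 0.00216), from 6138 ± 818 (SD, n = 3) to 1577 ± 362 (SD, n = 2). Tp63.L, the transcription factor of basal epidermal cells, fell by 1.81, cldn6.2.L, a claudin gene, by 1.26, krt19.S by 1.02 and epcam.L by 0.71. Epcam.L and itln1.L were named after their values were seen, and itln1.L, the intelectin of goblet cells, differed by 0.10 (SE 0.24). The median was 0.10 and the mean -0.03, of opposite sign, and camera made no call (adjusted p = 0.910). The counts moved with single arrays: 3 rose and 7 fell without ICD replicate 1, and 3, 2, 1 and 2 fell without ICD replicate 2, ICD replicate 3, ICD+FoxJ1 replicate 1 and ICD+FoxJ1 replicate 2.

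Of 24 ionocyte genes, 2 rose, 2 fell and 20 did not pass the test, and 5 rose and 4 fell when adjusted over the list alone. Atp6v0d2.L, a proton pump subunit gene, rose by 2.04 (SE 0.29, limma adjusted p = 0.00733) and ca12.L, a carbonic anhydrase gene, by 1.33. Both foxi4.2 homeologs, which encode forkhead factors of the ionocyte family, fell, the L copy by 1.74 and the S copy by 1.34. Another, dimmer probe set for foxi4.2.L differed by 0.39 and did not pass. The median was 0.26 (camera adjusted p = 0.2498). Without ICD replicate 1, 4 fell, without ICD replicate 2 or 3, 1 fell, without ICD+FoxJ1 replicate 1, 0 rose and 0 fell, and without ICD+FoxJ1 replicate 2, 1 rose and 0 fell.

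Of 25 neural genes, 0 rose, 4 fell and 21 did not pass, and 1 rose and 5 fell when adjusted over the list alone. The neural RNA-binding protein gene msi1.L fell by 1.18 and the tubulin gene tubb2b.S by 1.43. Ncam1.S, a neural adhesion gene, and snai2.S, a neural crest gene, were at background on both arrays with FoxJ1 and fell at least 1.93-fold and at least 1.95-fold. The median was -0.07 (camera adjusted p = 0.231). Camera placed the list lower without ICD replicate 1 (adjusted p = 0.0181, and 2 rose and 7 fell) and without ICD+FoxJ1 replicate 2 (adjusted p = 0.0496, and 0 fell). Both calls were lost, with an adjusted p = 0.492 and an adjusted p = 0.590 with an estimated correlation. In this list 2 fell without ICD replicate 2 or 3 and 0 without ICD+FoxJ1 replicate 1.

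Of 19 genes of mesoderm, muscle, blood and endoderm, 1 rose and 1 fell, with the same counts, 1 and 1, when adjusted over the list alone, and 17 did not pass. Myod1.L, the muscle regulator, rose by 1.21 from a level near background, 21.2 ± 0.557 (SD, n = 3), to 73.95 ± 36.1 (SD, n = 2), and ckm.L, muscle creatine kinase, fell by 1.29, with dimmer probe sets at -0.98 and -1.54 that did not pass. In this list 2 rose without ICD replicate 1, 0 rose without ICD replicate 3, 0 rose and 0 fell without ICD+FoxJ1 replicate 1, and 0 fell without ICD+FoxJ1 replicate 2. The median was 0.10 (camera adjusted p = 0.713).

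Of 14 tubulin and tubulin modification genes, 0 rose, 2 fell and 12 did not pass, and 3 rose and 2 fell when adjusted over the list alone. Tubb2b.S and tubb.L (-0.98) fell, the latter with a second probe set at -0.45 that did not pass, whereas tubb4b.L, the beta tubulin of cilia, differed by 0.91 (SE 0.26, limma adjusted p = 0.0794). The median was -0.15 and the mean 0.01 (camera adjusted p = 0.767). Without ICD replicate 1, 1 rose, without ICD replicate 2 or 3, 1 fell, and without either array with FoxJ1, 0 fell.

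Of 10 left-right and nodal cilium genes, 0 rose, 2 fell and 8 did not pass, and 1 rose and 3 fell when adjusted over the list alone. Those that fell belong to Hedgehog signalling: gli3.L, a transcription factor, at background on both arrays with FoxJ1, fell at least 2.86-fold, and smo.L, the signal transducer, fell by 1.31, with a dimmer probe set at -0.83 that did not pass. Without ICD replicate 1, 4 genes fell, and without either array with FoxJ1, 0 fell. The median was -0.24, or -0.11 with the 3 genes at background set to their bounds (camera adjusted p = 0.344).

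Of 70 cell cycle genes, 0 rose, 7 fell and 63 did not pass, and 8 fell when adjusted over the list alone. Mcm5.L, of the replicative helicase, fell by 1.35 (SE 0.22, limma adjusted p = 0.0113), from 547 ± 65.0 (SD, n = 3) to 204 ± 0.424 (SD, n = 2). Top2a.L, a topoisomerase gene, fell by 1.26 (its dimmer probe set, at -0.39, did not pass), ccnb3.S, a cyclin gene, by 1.24 and aurka.L, a mitotic kinase gene, by 1.04. The median was -0.49 (camera adjusted p = 4.97e-07), with an adjusted p = 0.308 with an estimated correlation. Without ICD replicate 1, 1 rose and 10 fell, without ICD replicate 2 or 3, 2 fell, and without either array with FoxJ1, 0 fell.

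Of 66 ribosomal protein genes, 0 rose, 2 fell and 64 did not pass, and 0 fell when adjusted over the list alone. These were rps12.L, which fell by 1.00, and rpl10a.S, which fell by 0.73. The median was -0.39 (camera adjusted p = 2.39e-08), with an adjusted p = 0.439 with an estimated correlation. With any array but ICD replicate 1 left out, 0 fell, and 4 fell with the labelling batch as a block. Of 29 stress and immediate early genes, 2 rose, 0 fell and 27 did not pass, and 4 rose and 1 fell when adjusted over the list alone. Cebpb.L, a transcription factor of the acute response, rose by 2.30 and hsp70.L, a chaperone gene, by 2.06. Without ICD replicate 1, 4 rose and 1 fell, and without ICD+FoxJ1 replicate 1, 1 rose. The median was 0.24 (camera adjusted p = 0.126).

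The labelling batch crossed the groups, and with it as a block 585 probe sets changed in limma, 541 of them among the 868. Median log2 differences on the arrays with poly-A control signal and on those without were 4.29 and 3.36 for the axoneme structure list, 2.70 and 2.16 for the dyneins, 1.69 and 1.12 for intraflagellar transport, 0.37 and 0.11 for the centriole list, -0.54 and -0.49 for the cell cycle and -0.36 and -0.51 for ribosomal proteins. For the tubulins they were -0.21 and -0.25, for the left-right list -0.37 and -0.07, for ionocytes 0.34 and 0.03, for epidermis 0.10 and 0.08, for the Notch list 0.16 and 0.17, for neural genes 0.01 and -0.50, for mesoderm 0.06 and 0.14 and for stress genes 0.21 and 0.13. With the block, 25 axoneme structure genes (median 3.86), 12 dynein genes (2.60), 9 intraflagellar transport genes (1.47) and 3 centriole list genes (0.26) rose, and 4 cell cycle genes (-0.49) and 4 ribosomal protein genes (-0.41) fell. Of the ionocyte list 1 rose and 1 fell with it, of the neural list 2 fell, and of the mesoderm list 0 rose.

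Single arrays moved the count of changed probe sets: it was 1387 without ICD replicate 1, 588 without ICD replicate 2 and 584 without ICD replicate 3. Without either array with FoxJ1 a single one is left, which makes the test less able to call changes. The smaller counts given without those arrays may reflect this as well as the arrays themselves. Of the 66 named genes past the threshold, 0 lost the call without ICD replicate 1, 10 without ICD replicate 2 and 13 without ICD replicate 3. More lost it without an array with FoxJ1, where a single array was left in that group. All 77 kept their direction in every alternative that tested them. The groups did not overlap in any of the 77, so leaving arrays out could not turn a direction.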

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

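The control probe sets below were set against each other only after the result was seen. The array carries control probe sets for Gapd, a glycolytic enzyme, and for beta actin, which entered no comparison. All 3 Gapd control probe sets drew attention because each lay higher on both arrays with FoxJ1 than on every ICD array. Among all tested probe sets 21.2% did so, and the 3 sets are for the same gene. The middle set was separated narrowly, at 356.2 on ICD+FoxJ1 replicate 1 against 352.5 on ICD replicate 3. The mean signals of the Gapd sets with FoxJ1 were 622 (3' end), 188 (5' end) and 546 (middle), against 336, 109 and 264 with ICD alone. Their log2 differences were 0.86, 0.73 and 0.96 as deposited, 0.84, 0.68 and 0.94 after quantile normalization, and 0.80, 0.67 and 0.90 with arrays scaled to the same median. The actin controls lay the other way under the same 3 scalings, with deposited differences of -1.30, -0.92 and -0.51, although the middle probe set overlapped between the groups. The ratio of the 3' to the 5' Gapd probe set was 2.75, 3.80 and 2.80 on the ICD arrays and 2.76 and 3.87 with FoxJ1. For actin it was 0.245, 0.217 and 0.181 on the ICD arrays and 0.205 and 0.122 with FoxJ1, lowest on ICD+FoxJ1 replicate 2. No explanation was tested for these values.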

How the results depend on the processing

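The fits with the labelling batch as a block and of the arrays with poly-A controls alone were chosen after the result was seen, and the other alternatives were planned. No named gene changed direction: of 1142 values, 963 stayed on their side of the threshold, 162 no longer passed and 17 newly passed. That no direction changed was largely fixed beforehand, as the groups did not overlap in any of these genes. With the replicate block, 316 probe sets changed (243 higher and 73 lower), all of them at least 2-fold, of which 297 were among the 868, and 7 intraflagellar transport genes rose. There the adjusted p of fry for the axoneme structure list was 0.345, and on the arrays with poly-A controls alone 0.439. The labels do not say whether equal numbers mark a pair, and the samples were treated as sharing a number only. Deviations of same-numbered arrays correlated at -0.06 and -0.32 across probe sets. With 2 arrays with FoxJ1 their deviations mirror each other, and the second pair crosses the labelling batch, so whether the numbers pair the samples stays open. On the arrays with poly-A controls, 189 probe sets changed, all of them at least 2-fold, and 4 intraflagellar transport genes rose. Fewer arrays were fitted there, and the cause was not tested for the others. With one replicate left out, between 148 (without ICD+FoxJ1 replicate 1) and 1387 (without ICD replicate 1) probe sets changed, 148 to 1093 by at least 2-fold. The members that rose numbered 16 to 27 in the axoneme structure list, 7 to 13 in the dynein list and 4 to 12 in the intraflagellar transport list. With ICD+FoxJ1 replicate 1 or 2 left out, the lone array is assumed to vary like the ICD group, and the test is less able to call changes. Camera with an estimated correlation ended the calls of the dynein (2.65), axoneme structure (3.95), intraflagellar transport (1.47), centriole (0.26), cell cycle (-0.49) and ribosomal protein (-0.39) lists, whose medians it leaves as they are. The neural median was -0.10 with no filter (camera adjusted p = 0.0303, and adjusted p = 0.664 with an estimated correlation), 0.12 with the dimmer 50% left out, 0.12 with the replicate block, 0.0037 on the arrays with poly-A controls and -0.50 to 0.19 with one replicate left out. The left-right median was 0.24 with the dimmer 50% left out and -0.47 to 0.17 with one replicate left out, and the mesoderm and endoderm median -0.016 to 0.21. The cause of these turns was not tested. Of 400 other member counts, 104 moved by over 1.5 times. Quantile normalization gave 976 changed probe sets, scaling to the same median 878, no filter 711, the dimmer 50% left out 649, no variance trend 871, and pseudocounts of 1 and 64 gave 798 and 896. With a pseudocount of 64, 543 changed by at least 2-fold. Signal over background limits the dimmest changes, as 57 of the higher probe sets were at background on all ICD arrays.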

Other observations

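Chosen after the result was seen were the matrix and ribosome biogenesis lists, the comparison of homeologs, the look at single ICD arrays, and the tests of the labelling batch, of the splits and of dim probe sets, whereas the test with matched random lists was written before its result. Of 53 measured genes of the extracellular matrix, its receptors and collagen processing, 25 fell with FoxJ1, 1 rose and 27 did not pass, with a median of -1.22. Since the list was written from these values, its camera adjusted p of 4.27e-14 is no independent evidence, and it was 0.0958 with an estimated correlation. Both homeologs of the fibronectin receptor subunit itgb1 fell, the S copy by 2.00 (SE 0.21) and the L copy by 1.73 (SE 0.20, with a dimmer probe set at -0.91 that did not pass), and dag1.L, dystroglycan, fell by 2.12. Fibronectin itself, fn1.S, fell by 0.95 by its brightest probe set, with dimmer ones at -1.25, which passed, and at -1.30 and -1.35, which did not, and the heparan sulphate polymerase gene ext1.L by 2.23. The gene that rose was fbln1.L, a fibulin (1.27). With the labelling batch as a block 21 of the 53 fell and 0 rose, so the call of fbln1.L was lost. Of 106 measured ribosome biogenesis genes, in a list also written from these values, 23 fell, 0 rose and 83 did not pass, with a median of -0.78 (adjusted p = 0.152 with an estimated correlation). Among those that fell, nop2.L fell by 1.57 and, by their brightest probe sets, dkc1.L fell by 1.16, fbl.S by 1.16 and ncl.S by 0.96. Dimmer probe sets of dkc1.L (-0.21 and 0.22), one of fbl.S (0.65) and one of ncl.S (-0.84) did not pass, and another of fbl.S (-1.11) did. With the batch as a block 5 fell.

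The homeologs of 3 glycolytic enzymes were compared, chosen after their values were seen, and the difference between copies passed the test in aldoa but not in eno1 or pkm. This test was a separate limma fit of the L minus the S log2 signal. It had no variance trend, and its p-values were adjusted over the 799 pairs alone. Aldoa.S differed by 1.72 (SE 0.21, limma adjusted p = 0.00371) and aldoa.L by -0.14 (SE 0.30), and the difference between the copies was -1.87 (SE 0.30, limma adjusted p = 0.0318). For eno1 the S copy differed by 1.86 and the L copy by 0.17 (difference -1.69, limma adjusted p = 0.0629), and for pkm the L copy by 1.38 and the S copy by 0.35 (difference 1.02, limma adjusted p = 0.0629). Over 799 pairs, the L and S differences parted in 17 after adjustment and in 135 at an unadjusted p under 0.05. In 22 pairs both copies were past the threshold, and all 22 moved in the same direction, whereas in 85 pairs 1 copy was, with the partner within 0.5 of 0 on the log2 scale in 32. A probe set of one copy can bind the other, which can make such differences smaller.

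ICD replicate 1 stood apart from the other ICD arrays as a whole. Its log2 signals correlated with theirs at 0.927 and 0.929, against 0.966 between those, and 65.3% of its probe sets exceeded background, the lowest share of the 5 arrays. Its background level, 28.4, was also the highest of the 5. That level was set by the same control probe set on every array, so the low share may reflect the level. Among the ICD arrays, ICD replicate 1 was lowest for 19 of 25 neural and 18 of 24 ionocyte genes. It was also lowest for all 27 axoneme structure genes, against 42.2% of all tested probe sets. Hes5.1.L had a signal of 660.7 there against 44.7 and 23, and 707.4 and 872.9 with FoxJ1, and the median log2 signal of 12 Hes, Hey and Nrarp genes was 7.01, 5.84 and 5.58 on the ICD arrays and 6.78 and 6.66 with FoxJ1. The axoneme structure genes ran the other way, with a median of 5.28 on that array against 6.40 and 6.74. These are values of single arrays, and no explanation was tested.

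The labelling batch was weighed as the source of the 868 changed probe sets. With the batch as a block 541 of the 868 kept their call. In all 868 both arrays with FoxJ1 lay apart from all ICD arrays, and the batch crosses the groups. A shift by batch alone does not give that pattern. The count of 541 was therefore largely fixed by the design and decides little about the batch. The split of the arrays by batch called 0 probe sets in limma (267 at an unadjusted p under 0.05), but it leaves the difference between the groups in the residual spread and decides nothing. Of the 10 splits of the 5 arrays into 3 and 2, 1 gave as many calls, the real one, and the highest of the others gave 1. Each of the others also mixes the groups and leaves the difference between them in the residual spread, so their few calls decide nothing. With 10 splits the share cannot fall under 0.05. The biological explanation, that FoxJ1 changes these genes, stays open.

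The lower medians of the cell cycle and ribosomal protein lists may come from array scaling or from a bias that follows signal. Random lists matched on mean signal had a median as low in at most 0.01% of 10000 draws, over both lists and with or without quantile normalization, which argues against such a bias as the whole cause. The matched lists had medians of -0.05 for the cell cycle and -0.17 for ribosomal proteins, so part of the ribosomal difference of -0.39 is shared with other bright genes. Matched draws take genes as independent, and the camera calls were lost with an estimated correlation.

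Dim probe sets were weighed as a reason why axoneme genes rose while most centriole genes did not pass. With 16 added to the signals, 21 of the 22 centriole list genes not past the threshold had a 95% interval that excluded 3.04, the lower quartile of the axoneme rises, but the added 16 narrows the intervals of dim probe sets. With a pseudocount of 1, all 17 of those genes above background on every array had one that excluded the quartile, then 3.51, and 11 had one that excluded a 2-fold rise. These genes were picked for not passing the threshold, which by itself puts the interval of a gene with a small spread below the quartile. The exclusion of the quartile therefore adds little to the missed threshold and does not decide whether dim signals hid a rise. The intervals of the other 5, at background on at least 1 array, excluded the quartile too, but so near the background a rise can stay unseen, and the question stays open for them too. Within the list 7 genes rose, with ccdc78.S (5.49) the largest rise of all probe sets tested, and the direct test of the lists gave p = 0.117 with an estimated correlation, so a biological difference between these groups of genes stays open.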
